A study of Mus musculus and Homo sapiens with 83 samples.

How the data were processed

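Cytoplasmic RNA of single cells was measured by AMAR-seq in 24 mESCs and 12 K562 cells, beside 4 K562 cells by whole-cell Smart-seq2 and 2 bulk K562 libraries. The deposited RNA values are raw counts of reads per gene, made by the authors for 1 library each. The deposited counts are whole numbers, and 5 closing lines of each library that sum reads on no gene, ambiguous, low-quality, unaligned or multiply aligned reads were kept out of all totals. The authors' notes name Trim Galore 0.6.7, Bismark, Bowtie2 2.2.9 and the hg38 and mm10 genomes. The aligner, counter, annotation and strand setting of the RNA reads are not given in the sources used here. The reads carry no molecular identifiers, so intervals and floors cover counting error only. The 41 DNA samples of the 83 in the series were not analysed here.

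Of 55401 mouse gene IDs, 55141 were matched to a name without the version suffix, 54349 of them with it. None of the 60623 human gene IDs was matched (0), so the 26 human gene lists and all named human genes were not evaluated. Positions came from a RefSeq table on the mm10 assembly. All pairs of libraries within a group were checked for repeats by a chi-square per degree of freedom over genes with at least 20 reads, and Smart-seq2 replicates 2 and 3 were counted as 1 library by their mean. No doublet caller was run, and no cell was removed.

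The labels give 1 cell per library and no separate cultures or batches, so cells were not used as replicates and no p-value, standard error or count of differing genes was computed. For each mESC day, counts were summed over cells and scaled to CPM. Ratios to day 0 were log2 values with a pseudocount of 1 CPM over genes with at least 20 reads over both days in at least 2 libraries, less the median over all such genes. Exact Poisson intervals at 95% confidence were given for CPM and exact conditional binomial intervals for ratios. A gene with 0 reads on a day was set against a floor of 3 reads over that day's sum, and one with 1 to 3 reads was given with its ratio and counting interval. These ratios and bounds are of plain CPM, without the pseudocount and without the median gene subtracted. They are thus not on the scale of the relative log2 ratios. The floor of 3 reads in a single mESC library was 0.183 to 0.767 CPM.

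The 34 mouse gene lists, with 456 members, covered pluripotency, lineages, feeder cells, metabolism, cell cycle and stress, and were fixed before the data were examined, as were the comparisons, the alternatives and the rule for named genes. Of these, 2 symbols on several gene IDs were left out. The median relative log2 ratio of a list with at least 5 measured members was placed among 10000 random lists drawn in 10 bins of expression, and lists beyond their central 95% were described as outside. Each comparison was recomputed without each cell in turn. Named genes were the 10 highest and 10 lowest relative ratios among genes with at least 20 CPM on the higher day, reads in at least 2/3 of its cells, a 2-fold ratio kept without any 1 cell and a higher median over cells, and up to 4 members of each list described, those with the largest ratios meeting the first 3 conditions or else those with the most reads. Predicted, clone and pseudogene names, ribosomal protein genes and mitochondrially encoded genes were excluded from the highest and lowest genes. Of the 10 lowest genes at day 9, 1 is not reported here, and of the list members the text names only examples. A few list members were named in addition after their values were seen.

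Genes per library were counted as the expected number with a read in a random 1000000 gene reads. Agreement between libraries was computed across genes as Pearson and Spearman correlation of log2(CPM + 1). The ratios and list calls were tested on simulated data with known changes. At a true 2-fold change, log2 0.94 to 0.95 with the pseudocount, the median estimate was 0.83 to 1.00, 11 to 15 of 16 changed lists were recovered, and 2 to 7 of 100 unchanged lists were called. At 4-fold, all 16 of 16 were recovered, and 5 to 8 of 100 unchanged lists were called. The simulated genes varied independently of each other, with the same dispersion and no difference in quality between cells. Members of a list that move together in 1 cell were not simulated, so these rates do not cover calls that arise in that way. The numbers of lists expected by chance also rest on random lists of unrelated genes. The alternatives were TMM and DESeq2 size factors, mean and median of CPM over cells, totals without mitochondrially encoded genes, pseudocounts of 0.1 and 10 CPM, minimums of 1 and 200 reads, and members without a read set at their bound. Alternatives added after seeing the data were leaving out day 0 cells above 10% mitochondrially encoded reads, totals without CT010467.1, and removal of each library's 50 most abundant genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, with R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.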

Results

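RNA was sequenced from single cells by AMAR-seq, a chip method that lyses the cell membrane, moves cytoplasmic RNA away from the nucleus on electrodes and makes full-length cDNA from it, while the nucleus is used for DNA methylation and accessibility. Of 42 RNA libraries, 24 were single E14 mouse embryonic stem cells (mESCs). The 6 day 0 cells came from culture on feeder cells with LIF, the cytokine that holds mESCs in self-renewal. The other mESCs came from undirected differentiation on gelatin without LIF or feeders, 7 at day 3, 6 at day 6 and 5 at day 9. The remaining 18 libraries were of K562, an established chronic myeloid leukaemia line: 12 AMAR-seq cells, 4 whole cells by Smart-seq2 and 2 bulk RNA libraries. The 41 DNA samples of the series were not analysed here.

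Reads on genes numbered 3913595 to 16367029 per mESC library. The medians, with the range over cells, were 7996262 (5800503 to 8801553) at day 0, 8682630.0 (6106763 to 11094070.0) at day 3, 10638120.0 (8894830.0 to 16367030.0) at day 6 and 7096529 (3913595 to 9656797) at day 9. A single gene, CT010467.1, was handled here as ribosomal RNA and stayed in all CPM totals unless stated. It took a median of 43.6% (34.3% to 58.1%) of gene reads at day 0, 53.4% (37.0% to 75.2%) at day 3, 30.3% (19.4% to 47.1%) at day 6 and 27.0% (13.0% to 73.1%) at day 9. Mitochondrially encoded transcripts took a median of 13.6% (3.29% to 24.2%) of gene reads at day 0, 3.53% (2.00% to 4.59%) at day 3, 5.72% (2.96% to 7.50%) at day 6 and 4.99% (2.41% to 18.6%) at day 9. At 1000000 reads per cell, the median number of genes with a read was 7418 (3455 to 9820.1) at day 0, 9019 (8436 to 10999) at day 3, 8965 (7207 to 11125) at day 6 and 11654 (8612 to 13299) at day 9. With CT010467.1 removed first, the medians were 8151 (3866 to 11818), 9561 (9302 to 12979), 9515.5 (7665 to 11634) and 12151 (8867 to 17016). Across 18478 genes, pairs of cells had a median Pearson r of 0.57 at day 0, 0.81 at day 3, 0.70 at day 6 and 0.71 at day 9 (Spearman 0.47, 0.72, 0.61 and 0.64; genes are not independent replicates).

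Each library of the time course was 1 cell, and no separate cultures were named, so each day was treated as a single sample and no test of a difference between days was made. Values are gene reads per 1000000 (CPM) of a day's summed cells with the 95% exact Poisson interval of the counting error, the number of cells with a read, and the range over cells. A gene group is given as the median log2 ratio of its members relative to the median gene, with its percentile among 10000 random lists of like expression. Lists beyond the central 95% of the random lists are called outside the random range, which is a description and not a test. The labels name no batch, so the day and the shared processing of a day's cells cannot be told apart. The 3 comparisons share the same 6 day 0 cells, of which cells 1, 2, 3 and 4 had 24.2%, 11.8%, 17.8% and 15.5% mitochondrially encoded reads and cells 5 and 6 had 3.29% and 4.09%. Values over the 2 day 0 cells under 10% are given beside them as an alternative chosen after the data were seen.

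Day 3 was compared with day 0 to show which genes differed early after LIF and feeders were withdrawn. Genes of DNA replication and of glycolysis were higher at day 3, and mitochondrially encoded transcripts and Egr1 were lower. Mcm2, a subunit of the replicative helicase, stood at 96.6 CPM (94.2 to 99.2; 7 of 7 cells) against 10.4 CPM (9.496 to 11.4; 5 of 6 cells). Ldha, the lactate dehydrogenase subunit of anaerobic glycolysis, stood at 4557 CPM against 705 CPM, with cells from 3029 to 6928 and from 309 to 1000.3 CPM. Egr1, a transcription factor of the immediate early response, stood at 2.02 CPM (1.68 to 2.41; 4 of 7 cells) against 272 CPM (268 to 277; 6 of 6 cells, 35.2 to 431 CPM).

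Over 14758 genes measured at both days, the median log2 ratio was 0.09. The DNA replication group had a relative median of 1.85 (percentile 100), with 10 of its 15 measured members at least 2-fold higher and 0 at least 2-fold lower. Ccne1, the cyclin of S phase entry, stood at 50.1 against 3.08 CPM, Mcm5 at 76.9 against 10.3 CPM and Mcm6 at 83.4 against 13.8 CPM. Glycolysis had 1.16 (percentile 100), with 9 of its 14 measured members at least 2-fold higher and 2 at least 2-fold lower. Eno1 stood at 4537 against 755 CPM and Pfkl at 156 against 18.5 CPM, while the glucose transporter gene Slc2a1 was lower, at 156 against 378 CPM. Mitochondrially encoded genes had -2.68 (percentile 0), and all 13 were at least 2-fold lower. mt-Nd1, a complex I subunit, stood at 765 against 8488 CPM. These 3 groups stayed outside the range without any 1 cell. Over the day 0 cells under 10% mitochondrially encoded reads, they had 1.31, 1.48 and -1.44 (percentiles 99.98, 100 and 1.24).

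Pluripotency genes went both ways. Pou5f1, the core pluripotency factor, was higher at 572 CPM (566 to 578; cells 254 to 847) against 137 CPM (cells 56.4 to 274). Klf2 and Esrrb, factors of naive pluripotency, were lower, at 15.97 against 100.02 CPM and 29.9 against 111 CPM. The naive pluripotency group as a whole had -0.82 (percentile 4.90), inside the range, and was outside it without any 1 of day 0 cells 1 and 5 (-1.21 to -1.05). The core pluripotency group had 0.87 (percentile 98.6), and came inside without any 1 of day 0 cells 4 and 5 (0.56 to 0.66). The LIF and STAT3 group, in which Jak1 stood at 23.2 against 2.35 CPM, had 1.12 (percentile 99.1), and came inside without day 3 cell 2 (0.80) or day 0 cell 4 (0.86). Over the day 0 cells under 10% these groups had 0.96 and -0.10 (percentiles 99.3 and 61.1).

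Another 9 groups were outside the range and depended on single cells. Higher was epithelial adhesion at 1.02 (percentile 98.0), which came inside without any 1 of day 3 cells 2, 3, 4, 6 and 7 (0.82 to 1.06) or any 1 of the day 0 cells (0.73 to 1.09). Also higher were the integrated stress response, with Asns at 175 against 32.2 CPM, at 0.75 (percentile 99.0), inside without day 0 cell 5 (0.68), mitosis at 0.47 (percentile 98.3), inside without any 1 of day 3 cells 1, 4 and 5 (0.40 to 0.52), and ER proteins at 0.48 (percentile 98.0), inside without day 3 cell 1 (0.34) or day 0 cell 5 (0.34). Lower were the two-cell-like genes, with Zscan4d at 1.20 against 33.3 CPM, at -2.29 (percentile 0.02), with no value without day 0 cell 3 (under 5 members left). Immediate early genes had -1.92 (percentile 0.21), inside without day 0 cell 6 (-1.31). Extraembryonic endoderm, with the basement membrane collagen Col4a1 at 1.45 against 35.9 CPM, had -1.002 (percentile 0.48), inside without day 0 cell 3 (0.16). Mesenchymal genes had -0.95 (percentile 1.85), inside without any 1 of day 3 cells 2, 3, 5, 6 and 7 (-0.89 to -0.70) or day 0 cell 6 (-0.34). Actin cytoskeleton and SRF/YAP targets had -0.92 (percentile 1.63), inside without any 1 of day 3 cells 1, 2 and 4 (-0.92 to -0.78) or day 0 cell 6 (0.34). Feeder fibroblast markers had -0.89 (percentile 3.92), inside the range and below it without day 3 cell 6 (-1.25) or any 1 of day 0 cells 2, 3 and 4 (-1.27 to -1.05). Their mean log2(CPM + 1) was 3.51 in day 0 cell 6, against 1.24 in the next day 0 cell. In all, 14 groups were outside the range, 8 higher and 6 lower, against 1.45 expected by chance, and 9 were outside over the day 0 cells under 10%. Of these, 7 were among the 14, and LIF and STAT3, extraembryonic endoderm, epithelial adhesion, two-cell-like genes, mitosis, stress response and ER proteins were not. The 15 groups inside the range lay from -0.96 to 1.14, of which 7 were outside it without some 1 cell, and 5 had too few measured members.

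Of single genes at 20 CPM or more, the largest relative log2 ratios were those of Aen, a nuclease gene, at 4.52 (36.0 CPM, cells 13.7 to 67.8, against 0.505 CPM), Dhodh of pyrimidine synthesis at 4.52 (27.7 against 0.176 CPM) and Gipc1 at 4.47 (55.0 against 1.36 CPM). Pja1 and Moxd1 had 3 reads each at day 0, with ratios of 355 (121 to 1723) and 329 (112 to 1599). Cdca5, Papss1 and the imprinted cell cycle inhibitor gene Cdkn1c had 4.38, 4.16 and 4.07. Dna2 and Pgpep1 had 4.20 and 4.06, and 1.35 and 2.06 without day 3 cell 6. Below Egr1, at -6.59, the lowest genes were Arntl of the circadian clock at -4.91 (1.05 against 56.6 CPM), Gpr4 at -4.83, Mn1 at -4.56 and Nup210l at -4.46. Zfp386 at -6.38 and Klb at -5.05 had -2.34 and -2.51 without day 0 cell 1, and Ulk4 at -4.28 had -1.61 without day 0 cell 5. Nlgn2 at -4.71 and Metap1d at -4.23 turned to 0.19 and 0.43, and Zfp386 came to -0.08, over the day 0 cells under 10%. Arntl had -3.86 without day 0 cell 5, Nup210l -3.38 without day 0 cell 4 and Col4a1, at -4.01, -2.85 without day 0 cell 2. Egr1 (ENSMUSG00000038418.7) lies on mm10 chromosome 18 from 34861207 to 34864956, Mcm2 (ENSMUSG00000002870.8) lies on chromosome 6 from 88883474 to 88898780, and Pou5f1 (ENSMUSG00000024406.16) lies on chromosome 17 from 35506032 to 35510777.

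**Figure D1:**
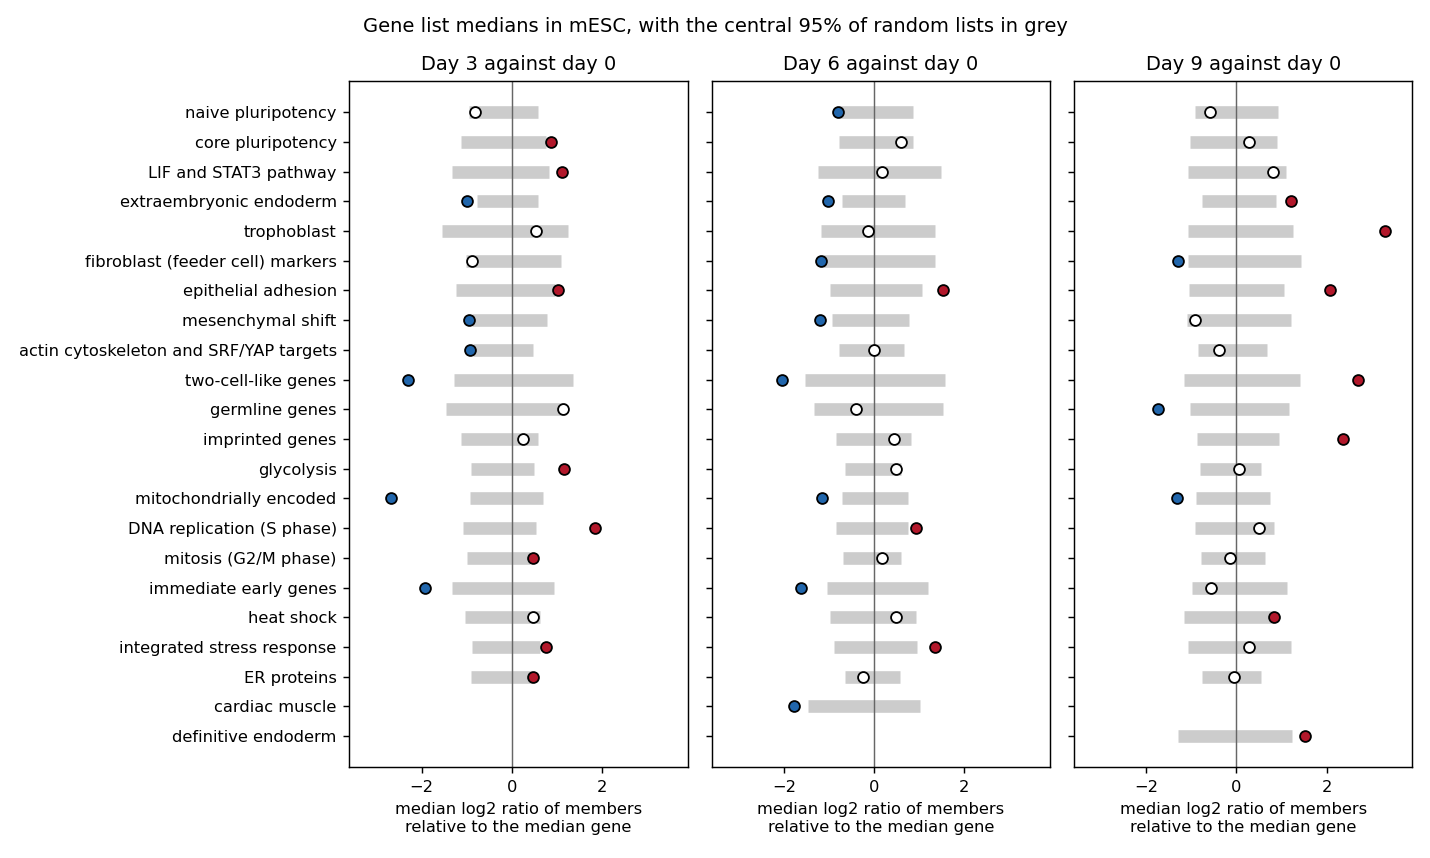
Points show the median log2 ratio of each gene group's members relative to the median gene at days 3, 6 and 9 against day 0, for groups outside the random range on at least 1 day, red above the central 95% of random lists (grey bars), blue below it and white inside it. DNA replication stood at 1.85 at day 3, epithelial adhesion at 1.54 at day 6 and trophoblast at 3.29 at day 9.

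Day 6 was compared with day 0 as the middle time without LIF. Genes of epithelial adhesion were higher at day 6 and genes of the mesenchymal shift were lower. Otx2, a homeobox factor of the epiblast, had 1 read in the day 0 cells and stood at 124 CPM (121 to 126; 6 of 6 cells, 8.88 to 285), a ratio of 5625 with a counting interval of 1009 to 222189. Car4, a membrane carbonic anhydrase, stood at 55.3 CPM (53.6 to 57.1; cells 15.4 to 109) against 0 reads, at least 839.7-fold higher against a floor of 3 reads over the day 0 cells. Cldn7, a tight junction claudin, stood at 64.9 against 3.62 CPM, and Klf2 at 10.2 against 100.02 CPM.

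Over 15117 genes, the median log2 ratio was 0.49. Epithelial adhesion had 1.54 (percentile 99.8), with 8 of its 11 measured members at least 2-fold higher and 2 at least 2-fold lower. Epcam stood at 153 CPM (cells 78.1 to 325) against 29.9 CPM, Rab25 at 22.8 against 0.264 CPM and Cldn3 at 24.5 against 0.835 CPM, while the cadherin gene Cdh1 was lower, at 26.2 against 105 CPM. The mesenchymal group had -1.19 (percentile 0.51), with 0 of its 10 measured members at least 2-fold higher and 6 at least 2-fold lower. Vim, the intermediate filament of mesenchymal cells, stood at 9.97 against 47.3 CPM and the matrix gene Sparc at 230.3 against 881 CPM. Both groups stayed outside the range without any 1 cell. With the median of CPM over cells in place of their sum, epithelial adhesion was no longer outside the range, and the mesenchymal group still was. The 2 groups had 2.13 and -2.09 (percentiles 99.9 and 0.02) over the day 0 cells under 10%. These are cells 5 and 6, of which cell 6 had the highest feeder fibroblast markers at day 0. With only cell 6 left out, the mesenchymal group had -1.73. Mitochondrially encoded genes had -1.16 (percentile 0.05), with 11 of 13 at least 2-fold lower, and stayed outside without any 1 cell, but had -0.18 (percentile 48.7) over the day 0 cells under 10%, a choice made on these same genes.

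The naive pluripotency group had -0.81 (percentile 2.07), with 1 of its 14 measured members at least 2-fold higher and 5 at least 2-fold lower, and came inside the range without any 1 of day 6 cells 2, 3, 4 and 5 (-0.70 to -0.64) or any 1 of day 0 cells 2, 3, 4 and 6 (-0.70 to -0.62). Within it, Esrrb stood at 52.8 against 111 CPM and Nanog was higher, at 59.5 against 26.3 CPM. Pou5f1 stood at 576 CPM. The formative group, to which Otx2 and the DNA methyltransferase genes Dnmt3a (375 against 64.2 CPM) and Dnmt3b (48.1 against 6.02 CPM) belong, had 0.57 (percentile 81.4), inside the range, with 6 of its 13 measured members at least 2-fold higher and 2 at least 2-fold lower. It was above the range without any 1 of day 0 cells 4, 5 and 6 (1.49 to 1.99), and over the day 0 cells under 10%. Fibroblast markers of the feeder cells were lower at -1.17 (percentile 2.21), and came inside without any 1 of day 6 cells 1, 2, 3, 4 and 6 (-1.16 to -0.87) or day 0 cell 6 (-0.40). The DNA replication group had 0.93 (percentile 99.2), with Mcm2 at 71.5 CPM, and came inside without day 6 cell 1 (0.78) or any 1 of day 0 cells 3 and 5 (0.63 to 0.68).

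Another 5 groups were outside the range and depended on single cells. The integrated stress response was higher at 1.35 (percentile 99.7), inside without any 1 of day 6 cells 1, 2 and 5 (0.04 to 1.12). Extraembryonic endoderm was lower at -1.02 (percentile 0.2), with Col4a2 at 1.35 against 37.0 CPM, inside without any 1 of day 0 cells 1, 2, 3, 5 and 6 (-0.66 to 0.02). Immediate early genes had -1.63 (percentile 0.17), inside without day 0 cell 6 (-0.94). Two-cell-like genes had -2.04 (percentile 0.54), inside without any 1 of day 0 cells 1 and 3 (-1.52 to 0.23). Cardiac muscle genes had -1.78 (percentile 0.65), with the myosin gene Myl7 at 16.9 against 91.6 CPM, and no value without any 1 of day 6 cells 4, 5 and 6 (under 5 members left) or any 1 of day 0 cells 2 and 3 (under 5 members left). In all, 11 groups were outside, 3 higher and 8 lower, against 1.55 expected by chance. That number was 6 without day 0 cell 3 and 7 over the day 0 cells under 10%. Of these 7, 5 were among the 11 on the same side, and two-cell-like genes were on the other side, at 1.31 (percentile 98.0). Extraembryonic endoderm, cardiac muscle, mitochondrially encoded, DNA replication and stress response genes were no longer outside. The 20 groups inside the range lay from -0.81 to 0.60, of which 2 were outside it without some 1 cell, and 3 had too few measured members.

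Among single genes, Hes6 stood at 74.7 CPM against 2 reads at day 0, a ratio of 1699 (470.2 to 14036). The kinase gene Pim2 had a relative log2 ratio of 5.62 (144 against 1.10 CPM), Tti1 5.56, Kif1a 4.99, Dhodh 4.92, Foxh1, a partner of SMAD factors in Nodal signalling, 4.88, Tbcd 4.87 and Nabp2 4.82. Lowest were Egr1 at -7.17 (1.67 CPM, 1.38 to 2.00), the peptide hormone gene Cck at -6.45 (0.234 against 75.9 CPM), Mobp at -5.42 and Hbegf at -5.35. Ankrd33b had 2 reads, a ratio of 0.000937 (0.000113 to 0.00339), and -2.16 as its relative log2 ratio without day 0 cell 1. Mn1 had 0 reads against 28.5 CPM, at least 648-fold lower. Zfp386, Kit and Disp1, at -6.70, -5.84 and -5.71, had -2.68, -2.14 and -2.83 without day 0 cell 1, and Il6ra at -5.91 had -3.04 without day 0 cell 2. Cck had -5.22 without day 0 cell 1, Mobp -3.99 without day 0 cell 5 and Tbcd 3.84 without day 6 cell 1. Otx2 (ENSMUSG00000021848.16) lies on mm10 chromosome 14 from 48656781 to 48667644, Car4 (ENSMUSG00000000805.18) lies on chromosome 11 from 84957754 to 84966054, and Cldn7 (ENSMUSG00000018569.12) lies on chromosome 11 from 69964779 to 69967886.

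**Figure D2:**
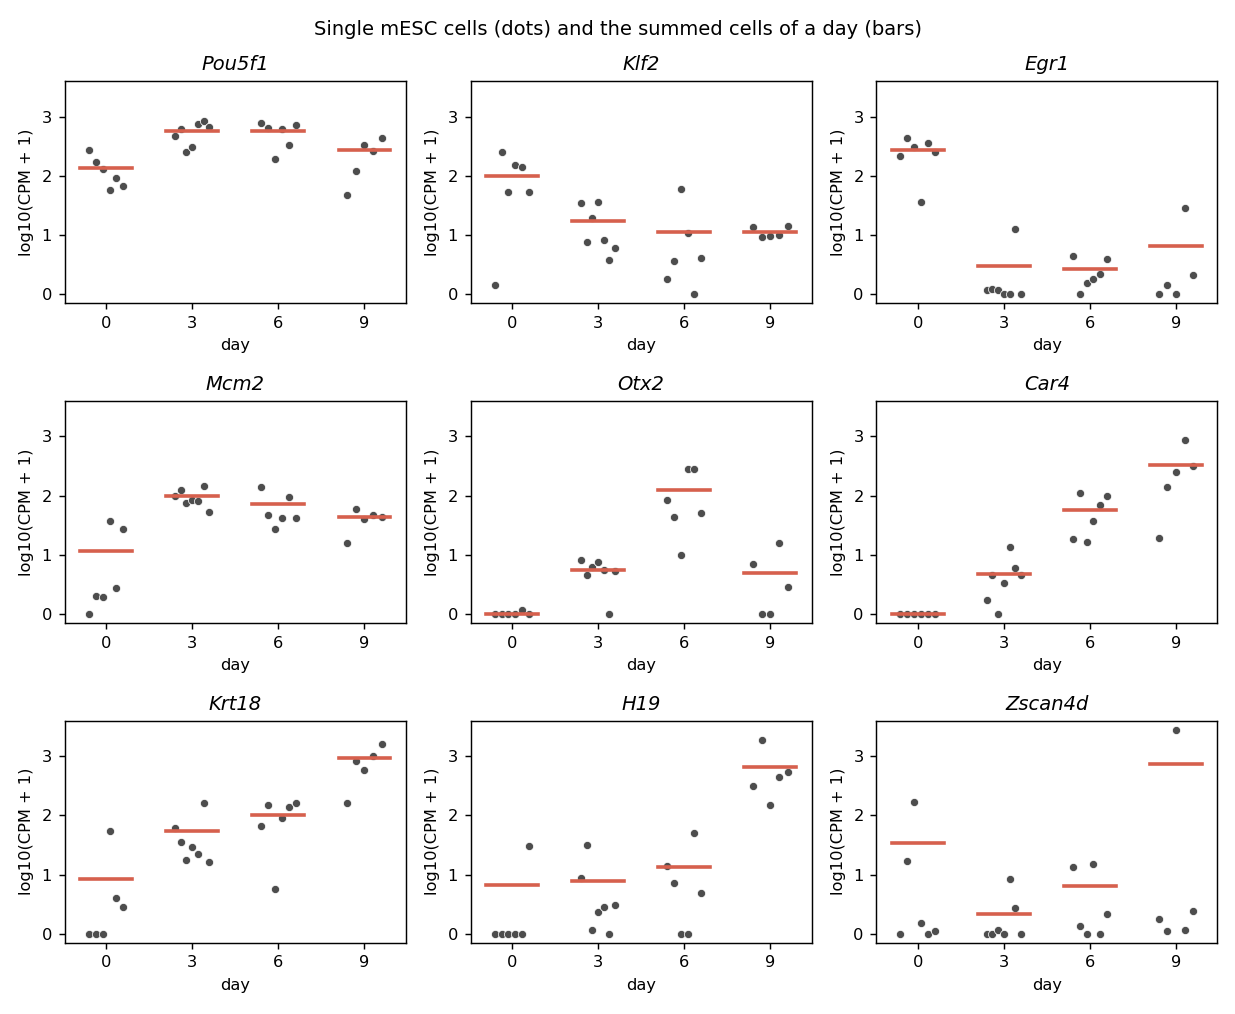
Dots show log10(CPM + 1) of 9 genes in each of the 24 single mESCs by day, and bars the value of a day's summed cells. Egr1 stood at 272 CPM over the day 0 cells and 2.02 CPM over the day 3 cells, Car4 had 0 reads at day 0 and 334 CPM at day 9, and Zscan4d reached 2755 CPM in 1 day 9 cell.

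Day 9 was compared with day 0 to show which genes differed after the longest time without LIF. Trophoblast, imprinted and epithelial genes were higher at day 9, and germline genes were lower. Krt18, a keratin of simple epithelia, stood at 921 CPM (912 to 931; 5 of 5 cells, 164 to 1609.8) against 7.60 CPM (3 of 6 cells). H19, an imprinted noncoding RNA, stood at 655 CPM (647 to 664; 5 of 5 cells, 150.3 to 1891) against 5.60 CPM in 1 of 6 cells. Car4 stood at 334 CPM (328 to 340.0; cells 18.1 to 869) against 0 reads, at least 5069-fold higher.

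Over 15512 genes, the median log2 ratio was 0.71. The trophoblast group had 3.29 (percentile 100), with 8 of its 11 measured members at least 2-fold higher and 1 at least 2-fold lower. Its keratins Krt8 and Krt7 stood at 609.8 (cells 144 to 983) against 13.0 CPM and at 94.96 against 0.593 CPM, and Hand1, a factor of trophoblast giant cells and early mesoderm, at 22.9 CPM against 0 reads, at least 347-fold higher. Eomes, which trophoblast stem cells need, was lower, at 3.45 against 8.33 CPM. The imprinted group had 2.36 (percentile 100), with 10 of its 14 measured members at least 2-fold higher and 0 at least 2-fold lower, and 1.54 without day 9 cell 4. Peg10 stood at 168 against 4.503 CPM, Cdkn1c at 41.5 against 0.967 CPM and Peg3 at 477 against 42.2 CPM. Epithelial adhesion had 2.07 (percentile 99.97), with Dsp at 38.8 against 1.34 CPM. The claudin gene Cldn6, which is in the definitive endoderm list and not in this one, stood at 133 against 3.32 CPM. The trophoblast, imprinted and epithelial groups stayed outside the range without any 1 cell. They had 3.10, 2.53 and 2.07 (percentiles 100, 100 and 99.9) over the day 0 cells under 10%.

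The germline group had -1.74 (percentile 0.09), with 0 of its 10 measured members at least 2-fold higher and 7 at least 2-fold lower. Of its members, Brdt stood at 0.932 against 28.0 CPM. The meiosis gene Stra8, which is not in the list and did not enter its median, stood at 0.740 against 49.2 CPM (cells 0.132 to 85.4). The mitochondrially encoded group had -1.31 (percentile 0.05), with 0 of its 13 measured members at least 2-fold higher and 8 at least 2-fold lower. Both groups stayed outside without any 1 cell, and over the day 0 cells under 10% both came inside, at -0.22 (percentile 24.2) and -0.23 (percentile 47.1), of which the second follows from a choice of cells made on these same genes. Day 9 cell 4 held 18.6% mitochondrially encoded reads.

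Another 5 groups were outside the range and depended on single cells. Extraembryonic endoderm was higher at 1.20 (percentile 99.7), with 14 of its 21 measured members at least 2-fold higher and 0 at least 2-fold lower, and came inside without day 9 cell 4 (0.66). Dab2, an endocytic adaptor of visceral endoderm, stood at 52.7 against 0.132 CPM and the endocytic receptor gene Cubn at 62.2 against 3.40 CPM. Definitive endoderm had 1.51 (percentile 99.2), inside without day 9 cell 4 (0.96) or day 0 cell 4 (1.26). Two-cell-like genes, with Zscan4c at 495 against 7.93 CPM, had 2.69 (percentile 99.98). They were below the range at -2.35 without day 9 cell 3, in which Zscan4c stood at 1866 CPM, and inside it at 1.40 without day 0 cell 5. Heat shock genes, with Hspa8 at 1109.7 against 180.1 CPM, had 0.84 (percentile 97.53), inside without any 1 of day 9 cells 1, 2 and 5 (0.57 to 0.96) or any 1 of the day 0 cells (0.56 to 0.86). Fibroblast markers were lower at -1.31 (percentile 0.91), inside without any 1 of day 9 cells 3 and 5 (-0.95) or day 0 cell 6 (-0.73). Over the day 0 cells under 10% the extraembryonic endoderm group had 1.95 (percentile 100) and the definitive endoderm group 0.99 (percentile 89.99). In all, 10 groups were outside, 7 higher and 3 lower, against 1.5 expected by chance, and 9 over the day 0 cells under 10%, of which 6 were among the 10 and definitive endoderm, germline, mitochondrially encoded and heat shock genes were not. The 20 groups inside the range lay from -0.92 to 0.81, among them naive pluripotency at -0.59 (percentile 11.3), which was below the range without day 9 cell 3 (-1.31), and 4 had too few measured members. Primitive streak and early mesoderm, which holds Hand1, was inside at 0.24 (percentile 78.1) and outside, higher, without day 9 cell 5 (2.02) or any 1 of day 0 cells 4 and 5 (1.19 to 1.35), over the day 0 cells under 10%, and with members without a read set at their bound (2.53). In all, 7 of the 20 were outside without some 1 cell. Klf2 stood at 10.2 CPM (cells 8.17 to 13.4) and Pou5f1 at 271 CPM (cells 46.2 to 432).

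Among single genes, Sfn, a 14-3-3 protein gene of epithelia, had a relative log2 ratio of 6.73 (209.9 against 0.220 CPM). Ttr, the transthyretin gene of visceral endoderm and liver, stood at 125 CPM in 4 of 5 cells (range 0 to 417) against 2 reads, a ratio of 2842 (786 to 23473). Cgrrf1 had 3 reads at day 0 and a ratio of 1666 (569.6 to 8081), and the homeobox gene Rhox6 stood at 67.3 CPM (cells 10.2 to 113) against 0 reads, at least 1021-fold higher. The iron exporter gene Slc40a1, Tmem37 and Pmp22 had 5.85, 5.68 and 5.64. Lowest were Cck at -6.59, Egr1 at -6.11 (5.45 CPM), Krt42 at -5.55 and Pi4kb at -5.06, and Mn1 had 2 reads, a ratio of 0.00192 (0.000233 to 0.00697). Zfp386 and Klb, at -6.52 and -5.36, had -2.50 and -2.85 without day 0 cell 1, and Cdc42ep2 at -5.46 had -2.63 without day 0 cell 2. Without day 9 cell 3, Slc40a1 had 4.06 and Cgrrf1, at 5.99, had 4.78. Without day 9 cell 4, Ttr, at 6.21, had 5.16 and Dab2, at 4.86, had 3.74. Without day 0 cell 1, Cck had -5.36 and Brdt, at -4.62, had -2.90. Krt18 (ENSMUSG00000023043.7) lies on mm10 chromosome 15 from 102028216 to 102032026, Krt8 (ENSMUSG00000049382.10) lies on chromosome 15 from 101996711 to 102004342, and H19 (ENSMUSG00000000031.16) lies on chromosome 7 from 142575530 to 142578146.

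The K562 libraries set AMAR-seq beside whole-cell Smart-seq2 and bulk RNA, to show how many genes the separated RNA of a single cell yields. At 1000000 reads per library, AMAR-seq cells showed a median of 9140.4 (6040.1 to 12638) genes, Smart-seq2 cells 11521 (10659 to 11775) and the 2 bulk libraries 13702 and 13728. Smart-seq2 replicates 2 and 3 differed by a chi-square of 2.06 per degree of freedom, above sampling noise but below the 4.71 between the bulk libraries and the 77.3 to 137 of the other Smart-seq2 pairs. They were counted as 1 library, which leaves 3. Gene reads were 5941786 (4094540.0 to 7452478) per AMAR-seq cell, 8334854 (4290751 to 9062258) per Smart-seq2 cell, and 8675014 and 6200149 in bulk.

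Genes at 1 to 10 CPM in bulk, 4863 in number, were detected at equal reads at a median of 40.1% per AMAR-seq cell (17.6% to 61.9%) and 61.4% per Smart-seq2 cell (53.9% to 63.6%). For the 5690 genes at 10 to 100 CPM the medians were 76.1% and 96.2%, and for the 1606 genes at 100 to 1000 CPM 98.6% and 99.9%. A median of 100% of the 129 genes at 1000 CPM or more was detected by either method. Of 12288 genes at 1 CPM or more in bulk, the 12 AMAR-seq cells together showed 12233 (99.6%) and the 3 Smart-seq2 libraries 11837 (96.3%), while 3 AMAR-seq cells showed a median of 95.3% (81.7% to 98.2% over 220 combinations). Every one of the 12 AMAR-seq cells had a read on 3249 genes of 23804 seen in any, and each of the 3 Smart-seq2 libraries on 11621 of 17313. These counts used all gene reads of each library and not equal reads. With more cells, genes seen in every cell can only fall and genes seen in any can only rise. Counts over 12 cells and over 3 libraries therefore do not compare the methods. The 50 most abundant genes took 53.8% (33.9% to 80.4%) of gene reads in AMAR-seq, 27.7% (21.8% to 30.4%) in Smart-seq2 and a median of 26.2% in bulk.

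Across 16440 genes, which are not independent replicates, pairs of AMAR-seq cells had a median Pearson r of 0.68 (0.47 to 0.86; Spearman 0.60), Smart-seq2 pairs 0.90 (Spearman 0.88) and the bulk pair 0.99 (Spearman 0.98). Single AMAR-seq cells had a median r of 0.78 with bulk (0.62 to 0.86; Spearman 0.72) and Smart-seq2 cells 0.86 (0.83 to 0.87; Spearman 0.83). Summed, the 12 AMAR-seq cells and the 3 Smart-seq2 libraries both had r of 0.88 and Spearman 0.85 with bulk. Sums of 3 AMAR-seq cells had a median r of 0.83 (0.72 to 0.89), and 13 of 220 were at or above the Smart-seq2 value. The files do not pair the 60623 human gene IDs with names, so no K562 gene is named. The 2 bulk libraries and 3 Smart-seq2 libraries limit what can be said of the spread within those methods.

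**Figure D3:**
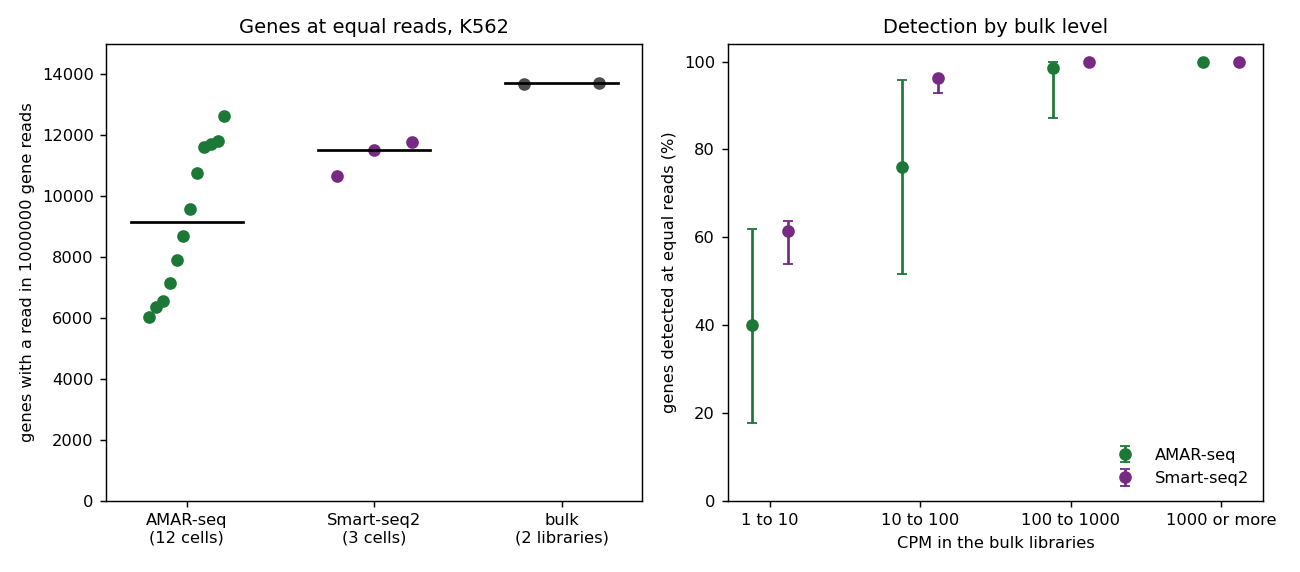
The left panel shows genes with a read in 1000000 gene reads for each K562 library (points) with the median of each method (lines), and the right panel the median percentage of genes detected at equal reads by their CPM in bulk, with the range over cells as bars. AMAR-seq cells ran from 6040.1 to 12638 genes, and genes at 1 to 10 CPM were detected at 40.1% in AMAR-seq and 61.4% in Smart-seq2.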

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

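The gene groups examined in this part were only those outside the random range on at least 1 day, so they were chosen on results of these same data. None of the values here was weighed against an explanation. In all, 116 sets of values were examined, each 1 measure or gene group over the mESCs of a day. Of these, 13 held a single cell far from the others. The sets overlap, as they come from the same cells, and K562 libraries were not examined. The number expected by chance was 5.8, which takes no account of the choice of gene groups or of the overlap.

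Day 3 cell 3 had 42.2% unaligned reads, far above the next cell at 22.8%. Day 6 cell 1 had 16367000.0 gene reads, far above the next at 11629800.0. Day 9 cell 4 had 18.6% mitochondrially encoded reads, far above the next at 6.72%.

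The other results are means of log2(CPM + 1) over a gene group in single cells. Two-cell-like genes stood at 6.97 in day 9 cell 3, with the next day 9 cell at 0.87, and at 3.47 in day 0 cell 3, with the next at 0.64. Fibroblast markers of the feeder cells stood at 3.51 in day 0 cell 6, with the next at 1.24. Mesenchymal genes stood at 2.89 in day 3 cell 1, the highest of that day, with the next at 2.04. In day 9 cell 1, glycolysis genes were lowest at 6.33 (next 8.32), ER proteins lowest at 4.56 (next 6.56), immediate early genes lowest at 1.28 (next 2.85) and germline genes highest at 1.62 (next 0.91). In day 6 cell 3, ER proteins were lowest at 5.12 (next 6.34) and integrated stress response genes lowest at 1.73 (next 3.44).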

How the results depend on the processing

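The settings that left out day 0 cells above 10% mitochondrially encoded reads, CT010467.1 or the 50 most abundant genes were chosen only after the data were seen. Across 12 settings per comparison, the 250 named gene values moved by less than 1 SD between cells in 2797 cases, by more in 188 and reversed in 13. The values of the 35 lists outside the random range moved by less than 1 SD in 357 cases, by more in 51 and reversed in 6. The named genes were chosen for keeping a 2-fold ratio without any 1 cell, and an SD between single cells is a loose limit. Few moves were thus built in, and these counts do not measure stability. With 1 cell left out, 11 of the 14 lists outside at day 3, 8 of 11 at day 6 and 5 of 10 at day 9 came inside, changed side or lost their value for at least 1 choice of cell. TMM and DESeq2 size factors left 14 lists outside at day 3, 10 at day 6 and 10 at day 9. Each scales a day's sum by a single factor, which largely cancels once the median gene is subtracted. Totals without mitochondrially encoded genes or CT010467.1 do the same. The calls could therefore hardly change, and these counts say little of the choice of scaling.

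At day 3, 14 lists were outside. With the median of CPM over cells, 7 were outside, 6 of them among the 14, and without the day 0 cells above 10% 9 were outside, 7 of them among the 14. At day 6, 11 lists were outside, against 7 without those cells, 5 of them among the 11 on the same side and 1 on the other, and 6 to 12 without 1 cell, where the 12, without day 0 cell 4, held 10 of the 11. Without those day 0 cells, which leaves 2 cells at day 0, values that reversed were at day 3 LIF and STAT3 (-0.10), extraembryonic endoderm (0.042), Nlgn2 (0.19), Metap1d (0.43), Hormad1 (-0.10) and Idi1 (0.39). At day 6 they were two-cell-like genes (1.31), Pfkl (-0.19), Mcm7 (-0.15), Ccnb2 (-0.33), Hsph1 (-0.12) and Sqle (-0.41), and at day 9 Pfkl (-0.52), Ccnb2 (-0.69), Pdia3 (-0.14) and Sqle (-0.71). With the median of CPM over cells, two-cell-like genes reversed at day 6 (0.29) and day 9 (-0.17), and definitive endoderm at day 9 (-0.32). In that setting 8 lists were outside at day 6, 5 of them among the 11. Epithelial adhesion, DNA replication, stress response, fibroblast, cardiac muscle and two-cell-like genes were lost. Formative, endothelial and blood, and imprinted genes were new. At day 9, 9 were outside, 6 of them among the 10. Definitive endoderm, fibroblast, two-cell-like and heat shock genes were lost, and naive pluripotency, core pluripotency and primitive streak genes were new. Without 1 cell, extraembryonic endoderm ran from -1.47 to 0.16 at day 3 and -1.60 to 0.018 at day 6, actin and SRF/YAP targets from -1.22 to 0.34 at day 3, and two-cell-like genes from -2.44 to 0.23 at day 6 and -2.35 to 4.09 at day 9. The cause was not tested.

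Genes per library with at least 3 reads in place of 1 were 6798 at day 3, 7272 at day 6, 8291 at day 9, 9504 in Smart-seq2 and 10368 in bulk. At 1 CPM or more as deposited they were 10895 in Smart-seq2 and 12269 in bulk, at the lower depth tried 10677 and 12168, and without the 50 most abundant genes 14359 in bulk. These settings count fewer genes by construction, or more once abundant genes are gone. Across genes with at least 200 reads, r was 0.77 within day 3, 0.62 within day 6, 0.987 for the bulk pair, 0.85 within Smart-seq2 and 0.78 for Smart-seq2 against bulk. With log2(CPM + 10) it was 0.87 within day 3, 0.76 within day 6 and 0.995 for the bulk pair, and the cause was not tested. Removing cells under 100000 gene reads or 2000 genes removed 0 cells and says nothing. K562 list alternatives were not run because no list could be named. No paired analysis was possible because the numbers name cells and no test was made. For counting error alone, depth sets a floor of 0.183 to 0.767 CPM in single cells.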

Other observations

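The tests on cell cycle mix, on 1 day 9 cell, on library depth and on the AMAR-seq cells that stayed below Smart-seq2 were chosen only after the results were seen. Single cells differed within a day. In day 9 cell 3, the two-cell-like genes Zscan4c, Zscan4d and Zscan4f stood at 1866, 2755 and 1026 CPM and Zfp352 at 363 CPM, while no other day 9 cell was above 7.51 CPM for any of these. Day 0 cell 3 held Zscan4d at 165 CPM and Tcstv3 at 23.8 CPM. Day 9 cell 4 held genes of visceral endoderm, with Ttr at 417, the apolipoprotein gene Apoa1 at 130.3, alpha-fetoprotein gene Afp at 78.8, Sox17 at 31.8, Gata4 at 60.8 and Amn at 106 CPM. Fgf5 and Fgf8, growth factor genes of the epiblast and primitive streak, stood at 20.7 and 58.0 CPM at day 9 against 0 and 3 reads at day 0, and Fgf8 reached 167 CPM in day 9 cell 3.

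The DNA methylation machinery group was inside the random range at each day, with relative medians of 0.33, 0.60 and -0.54 (percentiles 90.5, 93.4 and 13.0). Of its 12 members, Dnmt3b and Tet2 were picked after their values were seen. Dnmt3b, a de novo methyltransferase, stood at 6.02 CPM at day 0, 44.7 at day 3, 48.1 at day 6 and 78.3 at day 9, and Tet2, an enzyme of demethylation, at 63.2, 13.4, 8.74 and 10.9 CPM. Sox2 (ENSMUSG00000074637.7), a core pluripotency factor on mm10 chromosome 3 from 34649995 to 34652461, had 0 reads in all 24 cells, and its span lies within that of Sox2ot. Cox4i1, Rpl13 and Tubb3, genes of respiration, the ribosome and neurons, also had 0 reads in all 24 cells, as did Gins2, whose span overlaps Gse1. As Cox4i1 and Rpl13 serve all cells, 0 reads in these files sets no limit on the expression of these genes. Each library holds its ambiguous reads apart from any gene (0.851% to 5.06% of reads in mESCs). The rule that assigned reads on overlapping genes is not given, and no explanation was tested.

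The DNA replication group was higher at day 3 than at day 0, with cell means of log2(CPM + 1) of at least 4.74 at day 3 and at most 3.82 at day 0. Day 0 cells with a high mitochondrial share were argued against as the whole cause, since without 4 of them the list stood at percentile 99.98 (relative median 1.31) over the 2 left. A different mix of cell cycle phases among the day 0 cells stays open. Here 0 day 0 cells reached the lowest day 3 cell, the mitosis list stood at percentile 98.3, and phase was not measured. Cell means of this kind fall where fewer genes are detected. Day 0 cells showed 3455 to 9820 genes at equal reads, and day 3 cells 8436 to 10999. Cell means of mitosis (at most 4.77 at day 0, at least 5.03 at day 3) and core pluripotency (4.90 and 5.00) also did not overlap. A difference of culture between the days may also account for the higher DNA replication group and was not tested.

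At day 9, extraembryonic endoderm, trophoblast and imprinted genes were higher than at day 0. For extraembryonic endoderm, 1 cell may account for the call, since without day 9 cell 4 the list stood at percentile 97.2 (relative median 0.66). For trophoblast and imprinted genes this was argued against, with a lowest percentile of 99.98 without any 1 day 9 cell (imprinted genes without cell 4, relative median 1.54). Low-quality day 0 cells were argued against for these lists, since against day 3 their lowest percentile was 99.82, with relative medians of 2.09, 2.84 and 1.24. Extraembryonic endoderm was itself lower at day 3 than at day 0, which raises its value against day 3. The comparison with day 3 was not repeated without day 9 cell 4. Epithelial adhesion, also higher at day 9 than at day 0, was inside the range against day 3, at 0.78 (percentile 91.9). The difference in time without LIF stays open as an untested biological explanation, and only 5 cells were measured.

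AMAR-seq cells showed fewer genes at equal reads than Smart-seq2 cells. At 1000000 reads the AMAR-seq median was 9140 genes against 10659 in the lowest Smart-seq2 library, with 5 of 12 AMAR-seq cells at or above it, and as the pattern is itself measured at equal reads this is no separate test of depth. The prediction written beforehand for a few genes taking most of the counts used each library without its 50 most abundant genes. If they were the cause, the AMAR-seq median would reach the lowest Smart-seq2 library. It did, at 11120 genes against 11066. It stayed below the Smart-seq2 median (11748) and is the mean of 2 cells on either side of that library (10741 and 11499). In a count chosen after the result, 6 of the 7 AMAR-seq cells below the lowest Smart-seq2 library stayed below it, at 6535 to 10741 genes. These 7 cells were picked as the lowest, so the count argues against this as the whole cause only in the 6 that stayed. For the lower median, a few genes taking most of the counts stays open. Absence of nuclear RNA from the AMAR-seq fraction stays open, because 0 human gene IDs had a name, and no biological explanation was tested, as both sets are of K562.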
